A study of Mus musculus with 8 samples.

How the data were processed

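RNA sequencing of polyA RNA from mouse heart ventricles was analysed from 8 libraries, 4 labelled WT and 4 labelled RBX2iCKO. Per the labels' protocols, the ventricles were minced in RNAlater, RNA was extracted with TRIzol, and Novogene made and sequenced the libraries. All 8 samples are labelled as tamoxifen-treated. The labels call the cell type cardiomyocytes, while the protocol describes RNA of the minced ventricle. Groups were taken from the genotype label, and replicate numbers only name the libraries. The labels do not state that each library comes from a separate mouse, so p-values measure the spread between these samples, which may be technical. Pairs of libraries within a group differed by more than counting noise, with chi-square per degree of freedom from 10.9 to 64.0.

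The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled to the counted fragments of the library) for 35275 genes. It has 1 column per library, and no columns were pooled here. The genome build was mm10 per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Gene symbols and coordinates come from GENCODE M21, made on the same build, in which 34490 gene identifiers (97.8%) were found. Among the genes tested, 62 had no entry there.

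FPKM is a share of the library, so a change in a few abundant transcripts moves the values of all other genes. The depth was read from the deposited FPKM, since low values of a gene are whole multiples of what 1 fragment is worth. The annotated length of 4318 genes gave the fragment total in each library's FPKM denominator, from 18513924 to 23043686. Of each total, 99.0% to 99.3% lay in genes whose whole fragments were recovered. The totals therefore count mainly fragments assigned to genes, and shares of fragments given below are shares of these totals. With a tolerance of 0.01, whole fragments were obtained for 99.8% of the tested genes and 96.8% of the expressed genes. At these totals, 1 fragment in a gene of 1 kilobase is worth 0.0434 to 0.054 FPKM.

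The log2(FPKM + 1) values were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean FPKM of at least 0.5 over the 8 libraries were kept, which left 13050. Log2 differences are RBX2iCKO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. Fold values are ratios of mean FPKM. The deleted gene and the library measures were also compared by a two-sided exact permutation test over 70 assignments, which cannot give a p below 0.0286.

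Gene lists were fixed before the data were examined. Of 45 lists, 44 were tested with limma's camera at a preset correlation between genes, with Benjamini-Hochberg adjustment over the 44. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time: Rnf7, then the 12 largest increases and the 12 largest decreases among protein-coding genes past the threshold whose groups did not overlap and whose higher group averaged at least 1 FPKM, then up to 4 members of each list with the smallest p. For marker lists the rule also took the members of highest mean FPKM. Genes singled out outside that rule are said to be so. Some genes that the rule takes are not reported here.

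Other settings chosen before the data were examined covered the pseudocount, the filter, median-of-ratios and quantile scaling, removal of mitochondrial-encoded genes, the series of title numbers as a covariate, array weights, other eBayes settings, a mean-variance weighted fit, a fold limit, the other list tests and leaving out each library. Added after the data were seen were limma voom on the recovered fragments, an estimated correlation after scaling, an exact permutation of the list medians and leaving out each library after scaling. A sex covariate was not run, because all 8 libraries had Xist and no Y-linked transcript of 4 examined exceeded 0.093 FPKM.

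The test was checked on simulated data for this comparison, with 13027 genes of which 200 were changed. It recovered 59.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, and called 6 unchanged genes. The simulation gave every gene 1 dispersion, 0.0157, taken from the WT libraries, and no shift of the median. In the data, chi-square per degree of freedom ran from 10.92 to 21.69 within WT and from 20.6 to 63.96 within RBX2iCKO. Recovery and false calls in the data may therefore be worse than in the simulation. Library tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.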

Results

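Transcripts were measured by RNA sequencing in heart ventricles of mice, 4 labelled as inducible cardiac knockouts of Rbx2 and 4 labelled WT. Deletion used Mer-Cre-Mer, a tamoxifen-activated Cre recombinase driven by the cardiomyocyte αMHC promoter. RBX2, also called SAG and encoded by Rnf7, is the RING subunit of cullin 5 ubiquitin ligases. The FPKM denominators were 18758692 to 23043686 fragments in the 4 RBX2iCKO libraries and 18513924 to 22558094 in the 4 WT libraries, with overlapping ranges (two-sided exact permutation p = 0.9429). The comparison asks how the ventricular transcriptome differs between these groups. Effects of Rbx2 loss cannot be told apart here from effects of the Cre transgene with tamoxifen, as set out under other observations.

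Rnf7 (ENSMUSG00000051234, chromosome 9, 96470937 to 96478675 on the minus strand of mm10) was lower in all 4 RBX2iCKO libraries. Its level was 37.3 FPKM ± 2.38 in WT and 7.15 FPKM ± 0.28 in RBX2iCKO (SD, n = 4 each), which is 19.2% of the WT level. The log2 difference was -2.23 (SE 0.07, limma adjusted p = 5.8e-07), and the exact permutation p was 0.0286, the smallest that 70 assignments allow. The values cover the whole gene, so they do not show which part is missing.

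Fetal and matrix genes rose in the RBX2iCKO ventricles, and genes of fatty acid oxidation fell. Of 13050 genes tested, 4374 were higher and 459 lower in RBX2iCKO as deposited. The median of all genes was itself higher by 0.21 on the log2 scale. After median-of-ratios scaling, which brought that median to 0.02, 1146 genes were higher and 1419 lower. All 1146 and all 459 were shared with the calls on deposited values, and 0 genes called in both had opposite signs. Scaling divided the WT libraries by 0.859 to 0.945 and the RBX2iCKO libraries by 1.072 to 1.118. That lowers almost every gene alike, so this overlap is largely set by construction. With mitochondrial-encoded genes removed, 2080 genes were higher and 711 lower. Mitochondrial-encoded transcripts took 23.8% ± 1.04 of counted fragments in WT and 16.9% ± 2.06 in RBX2iCKO (SD, n = 4 each, exact permutation p = 0.0286). The first principal component, with 53% of the variance, separated the groups, and RBX2iCKO replicate 3 lay apart on the second, at -30.9.

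**Figure D1:**
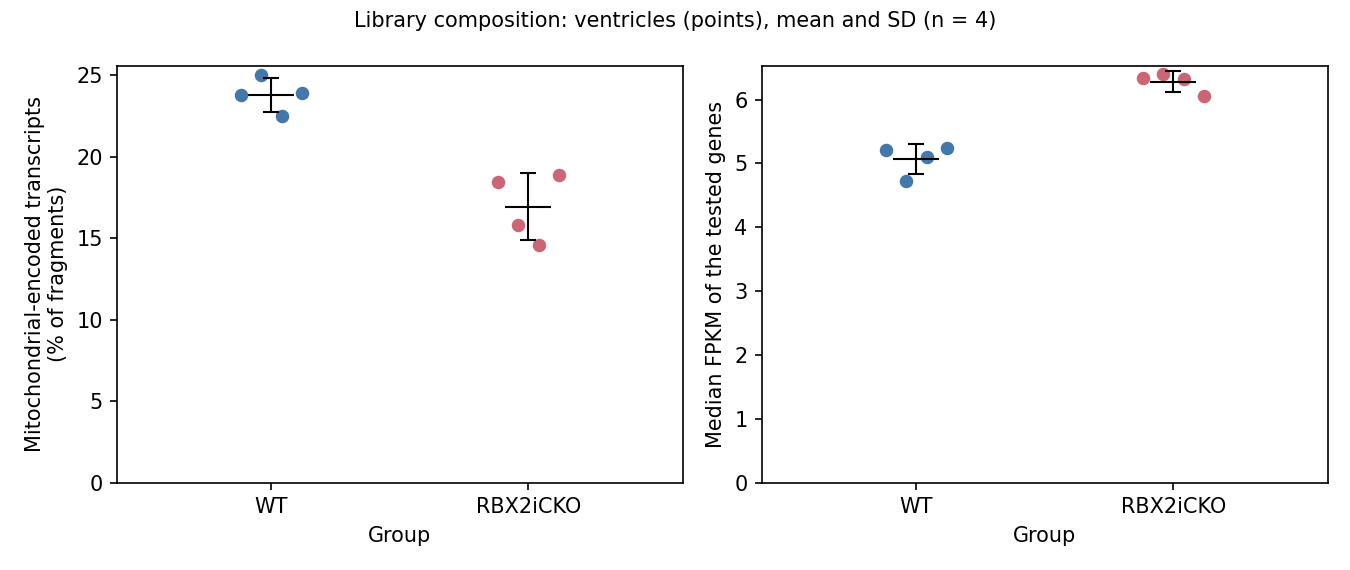
Share of counted fragments from mitochondrial-encoded transcripts (left, percent) and median FPKM of the tested genes (right), with points for libraries and bars for mean and SD (n = 4). The RBX2iCKO libraries lie between 14.6% and 18.87% mitochondrial fragments, all below the WT range of 22.51% to 25.05%, and their median FPKM of 6.05 to 6.41 lies above the WT range of 4.72 to 5.24.

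Genes of the fetal and stress programme of cardiac muscle were among the largest increases. Nppa, which encodes atrial natriuretic peptide, rose 36.5-fold, from 10.5 FPKM ± 7.54 to 384 FPKM ± 72.3 (SD, n = 4 each; log2 5.31, SE 0.44, limma adjusted p = 0.000388). Nppb, the B-type natriuretic peptide gene, rose 6.28-fold, Myh7, the beta myosin heavy chain gene, 8.83-fold, and Acta1, skeletal alpha-actin, 8.52-fold. Ankrd1, a stretch-responsive ankyrin repeat gene, rose from 324 to 1643 FPKM. Of 22 fetal and stress genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), and 11 rose after scaling. Camera placed the list above other genes (adjusted p = 0.000129), with an adjusted p = 0.267 with an estimated correlation. Nppa is also an atrial marker, and of 9 atrial markers 4 rose and 0 fell (4 and 0 adjusted over the list alone, 2 and 0 after scaling), with no camera call (adjusted p = 0.697). Atrial light chain Myl7, singled out after its values were seen, varied within both groups, from 0.422 to 237 FPKM in WT and from 1.32 to 361 FPKM in RBX2iCKO, and did not pass (adjusted p = 0.900). Reads of Myh7 and its antisense partner Mhrt cannot be told apart here, and Acta1 has close paralogs.

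**Figure D2:**
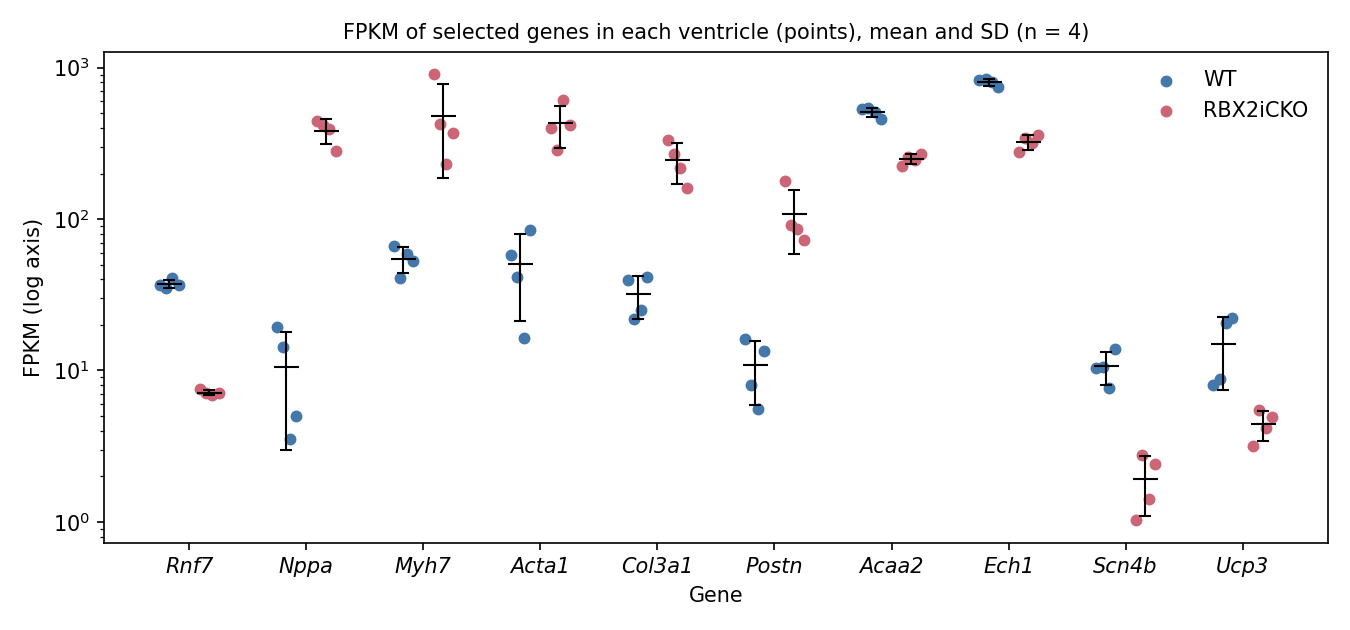
FPKM (log axis) of 10 genes, with points for libraries and bars for mean and SD (n = 4). Rnf7 falls from 37.3 to 7.15 FPKM on average, Nppa rises from 10.5 to 384 and Acaa2 falls from 509 to 249.

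Extracellular matrix genes rose together. Of 40 matrix and fibrosis genes, 36 rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 difference of 1.69, and 31 rose after scaling. Collagen type III, Col3a1, rose 7.68-fold, from 32.0 FPKM ± 10.1 to 246 FPKM ± 74.6 (SD, n = 4 each; log2 2.90, SE 0.26, limma adjusted p = 0.000497). Postn, the matricellular periostin gene, rose 9.93-fold, Eln, encoding elastin, 12.2-fold, and Mfap4, a microfibril-associated gene, 13.4-fold. The matrix gene Cilp and the secreted factor genes Sfrp2 and Angptl7 also rose. Cilp went from 2.54 to 30.5 FPKM, Sfrp2 rose 13.2-fold and Angptl7 7.21-fold, or 13.9-fold without WT replicate 1. The list ranked above other genes (camera adjusted p = 4.19e-11), with an adjusted p = 0.415 with an estimated correlation.

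Markers of fibroblasts rose as well. Of 13 fibroblast markers, some of which are also in the matrix list, 12 rose and 0 fell (12 and 0 adjusted over the list alone, 10 and 0 after scaling), among them Pi16, 3.40-fold, and Mfap5, 5.43-fold. These markers ranked above other genes (camera adjusted p = 3.27e-05), with an adjusted p = 0.415 with an estimated correlation. Of 16 endothelial markers 8 rose as deposited and 0 after scaling (13 adjusted over the list alone), including Tie1 and Vwf, whose calls were lost after scaling. Of 11 mural markers 2 rose, 1 of them Pdgfrb, and Abcc9 fell (2 and 1 adjusted over the list alone, 1 and 1 after scaling). Of 19 macrophage markers 7 rose and 0 fell (7 and 0 adjusted over the list alone), and 2 rose after scaling. Among the risers were Fcgr1, from 0.822 to 2.32 FPKM, and Ms4a7, from 0.893 to 2.42 FPKM, both low in WT. The more abundant C1qa, at 41.2 FPKM ± 10.3 in WT and 64.6 FPKM ± 25.3 in RBX2iCKO (SD, n = 4 each), did not pass (limma adjusted p = 0.164). The median of the macrophage markers was 0.56 while camera ranked them downward (adjusted p = 0.935), so the signs differ. Of 14 ventricular cardiomyocyte markers 1 rose and 3 fell (1 and 3 adjusted over the list alone, 0 and 6 after scaling), with a median 0.24 below that of all genes. Tnni3, cardiac troponin I, fell 1.39-fold, while Actc1, cardiac actin, rose 1.33-fold as deposited and did not pass after scaling. Camera placed this list below other genes (adjusted p = 7.87e-05), with an adjusted p = 0.267 with an estimated correlation.

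Genes of mitochondrial fatty acid oxidation fell. Of 28 such genes, 23 fell and 1 rose (23 and 1 adjusted over the list alone), and 24 fell after scaling. The median log2 difference was -0.57, which is 0.78 below that of all genes. Acaa2, the last enzyme of the beta-oxidation spiral, fell 2.04-fold, from 509 FPKM ± 35.4 to 249 FPKM ± 18.7 (SD, n = 4 each; log2 -1.03, SE 0.08, limma adjusted p = 0.000318). Decr1, needed for unsaturated fatty acids, fell 2.08-fold, Hadha, of the trifunctional protein, 1.74-fold, and Cpt2, a carnitine palmitoyltransferase, 1.71-fold. The gene that rose was Cpt1a, singled out after its values were seen. Outside the list, Ech1, an enoyl-CoA isomerase gene, fell 2.48-fold, and Acot1, which has near-identical paralogs, fell 3.15-fold. Camera gave an adjusted p = 6.39e-36, and an adjusted p = 0.126 with an estimated correlation, the smallest of any list.

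Other mitochondrial genes lay below the median of all genes. Of 12 mitochondrial-encoded genes 10 fell (11 adjusted over the list alone, 11 after scaling), and mt-Nd1 and mt-Nd2 fell by 0.64 and 0.59 on the log2 scale. Of 18 genes of the tricarboxylic acid cycle 9 fell and 0 rose (12 and 0 adjusted over the list alone), and 18 fell after scaling, with Idh3g and Suclg1 falling 1.28-fold and 1.29-fold. Of 18 genes of branched-chain amino acid breakdown 10 fell and 0 rose (11 and 0 adjusted over the list alone, 17 and 0 after scaling), including Aldh6a1 and Ppm1k. Camera placed these 3 lists below other genes (adjusted p = 1.97e-17, 8.35e-17 and 2.46e-16). With an estimated correlation the adjusted p was 0.141, 0.149 and 0.158.

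Few nuclear genes of the respiratory chain fell as deposited, and more fell after scaling. Of 36 nuclear genes of complex I 5 fell and 0 rose (0 and 0 adjusted over the list alone), and 17 fell after scaling. Of 25 genes of complexes II to IV 4 fell and 1 rose (4 and 1 adjusted over the list alone, 10 and 0 after scaling), with Sdha and Uqcrc1 falling 1.31-fold and 1.28-fold. Of 16 genes of ATP synthase 3 fell and 1 rose (2 and 1 adjusted over the list alone, 9 and 1 after scaling). The riser was Atpif1, the inhibitory factor of the enzyme, 1.96-fold. Camera gave adjusted p = 8.51e-09, 6.06e-08 and 6.73e-05 for these lists, and adjusted p = 0.415, 0.415 and 0.421 with an estimated correlation.

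**Figure D3:**
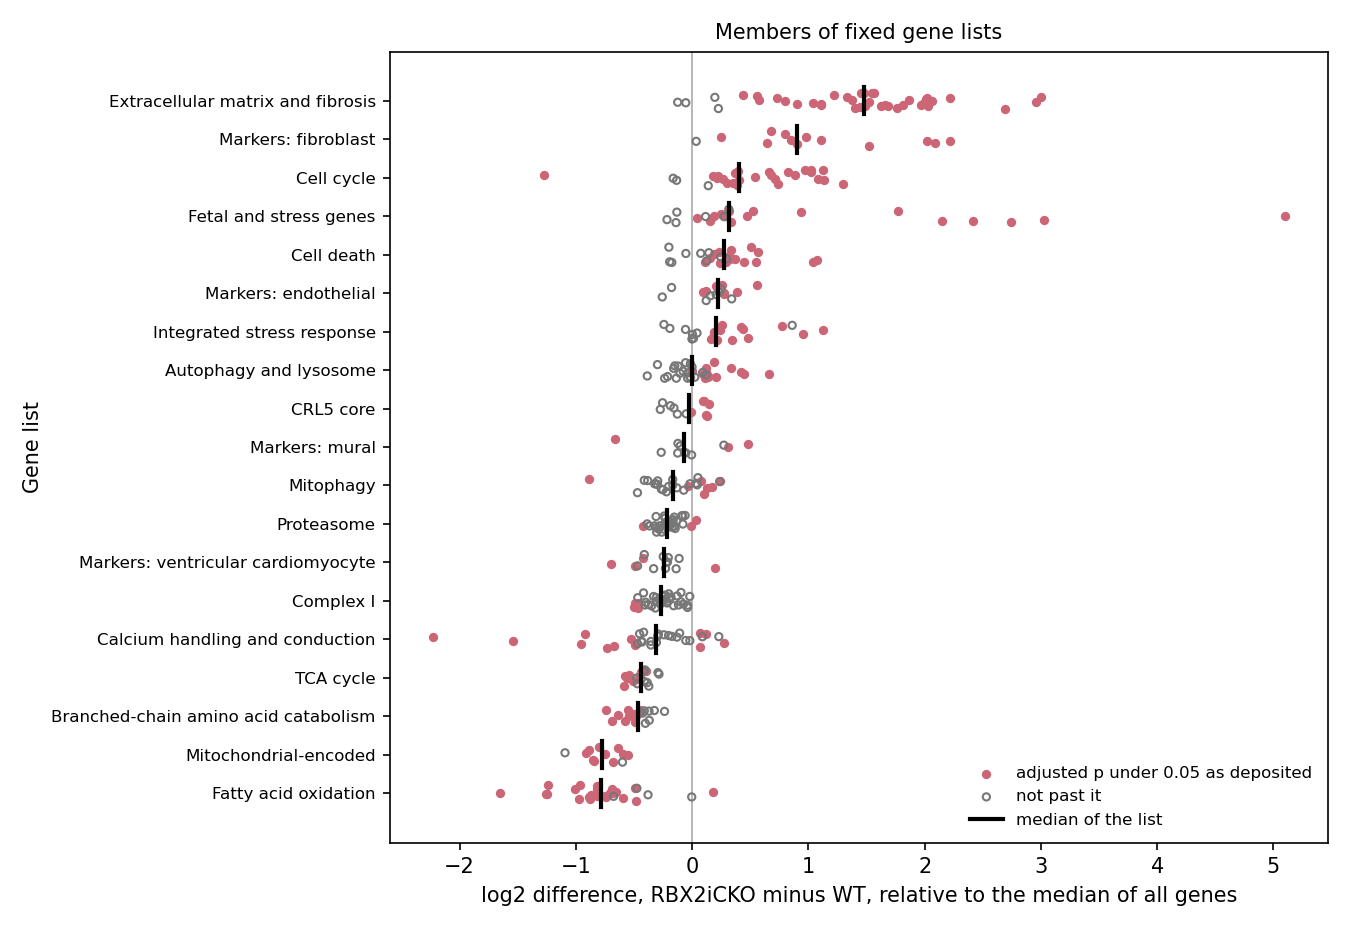
Log2 difference of each member of 19 gene lists, RBX2iCKO minus WT, relative to the median of all genes (horizontal axis, 0 at that median), with filled points past the threshold as deposited and black bars for list medians. The matrix list has a median 1.48 above and the fatty acid oxidation list 0.78 below the median of all genes.

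Of 27 mitophagy genes 6 rose and 1 fell as deposited (5 and 1 adjusted over the list alone), and after scaling 0 rose and 7 fell. Pink1, the kinase that marks damaged mitochondria, fell 1.58-fold, from 297 FPKM ± 8.35 to 189 FPKM ± 37.5 (SD, n = 4 each; log2 -0.68, SE 0.13, limma adjusted p = 0.00646). The mitophagy receptor gene Bnip3l and the deubiquitinase genes Usp30 and Usp8 rose 1.28-fold, 1.48-fold and 1.33-fold as deposited and did not pass after scaling. Camera ranked the list downward (adjusted p = 0.0489) although its median was 0.05, with an adjusted p = 0.267 with an estimated correlation. A list of 12 genes covered the cullin 5 ligase core, NEDD8 enzymes and adaptors, some (such as Rbx1 and Ube2m) not particular to cullin 5. Of these 12 genes 6 rose and 0 fell as deposited (6 and 0 adjusted over the list alone), including Elob and Cand1. After scaling 0 rose and 1 fell, Cul5 itself (scaled log2 -0.29, limma adjusted p = 0.0273; -0.06 and 0.456 as deposited), singled out after its values were seen, and camera made no call (adjusted p = 0.897). Of 30 SOCS-box substrate receptors 8 rose and 3 fell as deposited (8 and 3 adjusted over the list alone), and 3 rose and 6 fell after scaling. Asb15 fell 1.70-fold and Spsb2, which overlaps the abundant gene Tpi1 on the opposite strand, rose 2.20-fold. Of 33 genes of autophagy and the lysosome 13 rose and 0 fell (13 and 0 adjusted over the list alone), and 3 rose and 3 fell after scaling. The median of this list equalled that of all genes, and camera made no call (adjusted p = 0.251). Its rise as deposited is therefore not set apart from the shift of all genes. The lysosomal enzyme gene Hexa rose 1.48-fold, from 31.8 FPKM ± 2.29 to 47.0 FPKM ± 1.72 (SD, n = 4 each).

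Several ion channel and calcium genes fell. Scn4b, a sodium channel beta subunit, fell 5.56-fold, from 10.6 FPKM ± 2.58 to 1.91 FPKM ± 0.823 (SD, n = 4 each; log2 -2.02, SE 0.22, limma adjusted p = 0.000952). Of 31 genes of calcium handling and conduction 8 fell and 4 rose (8 and 4 adjusted over the list alone), and 17 fell after scaling. Atp2a2, the sarcoplasmic reticulum calcium pump, fell 1.63-fold, and the potassium channel genes Kcnv2 and Kcnj3 fell 4.48-fold and 1.74-fold. Together they ranked below other genes (camera adjusted p = 2.97e-09), with an adjusted p = 0.141 with an estimated correlation. Other large decreases were Ces1d, a carboxylesterase of a near-identical family, 3.37-fold, Ucp3, 3.37-fold, Fbp2, a muscle fructose bisphosphatase, 2.72-fold, and Mylk4, 2.48-fold. Pfkfb1 and Amy1, the latter of a near-identical family, fell 3.08-fold and 2.98-fold.

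Genes of the integrated stress response rose in part. Of 22 such genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), and after scaling 7 rose and 1 fell. Mthfd2, a mitochondrial folate enzyme, rose 3.21-fold, Gdf15, a stress cytokine gene, 4.02-fold, Trib3 1.89-fold and Atf5 1.58-fold. Camera gave an adjusted p = 0.0266, and an adjusted p = 0.514 with an estimated correlation. Of 21 genes of mitochondrial protein quality control 5 fell and 1 rose (5 and 1 adjusted over the list alone, 14 and 0 after scaling), with Hspa9, the mitochondrial HSP70, falling 1.24-fold. Of 37 mitochondrial ribosome genes 4 fell and 3 rose (3 and 1 adjusted over the list alone, 17 and 0 after scaling), with Mrpl45 falling 1.29-fold. Camera placed both lists below other genes (adjusted p = 1.46e-07 and 3.27e-05), with adjusted p = 0.202 and 0.415 with an estimated correlation.

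The gene with the largest increase was Esr1, the estrogen receptor alpha gene, from 0.757 FPKM ± 0.883 to 331 FPKM ± 51.5 (SD, n = 4 each; log2 7.66, SE 0.27, limma adjusted p = 1.49e-06). The ratio of means was 436, or 1024 without WT replicate 1. In Mer-Cre-Mer, Cre is flanked by ligand-binding domains of the mouse estrogen receptor, and the FPKM values do not show which part of Esr1 the fragments came from. High Esr1 and low Rnf7 went together in all 8 libraries, which bears on every difference between the groups. Camera at the preset correlation called 6 lists higher and 18 lower in all. With an estimated correlation 0 lists passed, against 7 at an unadjusted p under 0.05, and fry, which tests a list by itself, called 16 higher and 5 lower.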

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

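The far-sample check was fixed before the data were examined, and the tests of explanations here were chosen after the results were seen, except the gene length test. Within each group of 4, the farthest library was compared with the range of the others for 180 sets of values, and 9 stood apart. Chance alone gives about 9, so the number of them carries no weight.

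WT replicate 3 stood above the other WT libraries for Nppb, at 99.23 FPKM against 34.23 to 38.83. The same library was highest for Pink1, at 309.69 FPKM against 291.85 to 294.74, for the macrophage gene Ms4a7, at 1.43 FPKM against 0.68 to 0.74, and for Top2a, at 0.89 FPKM against 0.52 to 0.58. WT replicate 2 was lowest for Hexa, at 28.4 FPKM against 32.61 to 33.42. RBX2iCKO replicate 3 was highest for Ankrd1, at 1953.14 FPKM against 1502.6 to 1561.52, and for the interferon-induced gene Rsad2, at 27.96 FPKM against 5.11 to 7.53. RBX2iCKO replicate 1 was highest for Usp8, at 16.41 FPKM against 14.36 to 14.7, and for Hif1a, at 28.78 FPKM against 20.88 to 21.75.

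Far more genes were higher than lower in RBX2iCKO, 4374 against 459. If the smaller mitochondrial share were the whole reason, removing those genes would bring the median of the others to 0, but it stayed at 0.12, and at 0.11 to 0.13 with any library left out. That share therefore accounts for part of the shift from 0.21 at most. Gene length bias is argued against, since the median was 0.21 over the shortest 4350 genes and 0.22 over the longest 4350. At a mean FPKM of at least 5, 2478 genes were higher and 375 lower, so the excess was not confined to low transcripts. What remains open includes a real rise of many transcripts, or a loss of other abundant transcripts, and FPKM without an external standard cannot separate these.

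Fibroblast markers rose and fatty acid oxidation genes fell. A lower share of cardiomyocytes as the only change would raise markers of all other cell types alike, but after scaling fibroblast markers exceeded endothelial markers by 0.73 ± 0.27 and mural markers by 0.97 ± 0.33 (log2, SD over the 4 RBX2iCKO libraries). It would also lower fatty acid oxidation genes no more than cardiomyocyte markers, but they lay -0.5 ± 0.11 from them. These SDs do not count the spread between the WT libraries, so they understate the uncertainty of the differences. A change within fibroblasts, or in their number, and a change within cardiomyocytes remain open as hypotheses. A lower share of cardiomyocytes alongside such changes is not excluded, since the cardiomyocyte marker median lay at -0.33 after scaling.

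The real grouping of the libraries gave more gene calls than any other grouping, which did not hold for list calls. Of 35 splits of the 8 libraries into 4 and 4, 1 gave as many as 4833 genes, the real split, and the highest of the others gave 4. After median-of-ratios scaling 1 of 35 gave as many as 2565, and the highest of the others gave 1. Every other split mixes the genotypes, which adds their difference to the spread within groups and holds gene calls down. The low counts show that the real split ranks first, but they do not measure false calls. For lists at the preset correlation, 7 of 35 splits gave as many as the real 24, and the highest of the others gave 27. All other splits that reached 24 kept most libraries of a genotype together, so they carry part of the group difference. Splits with equal numbers of each genotype on both sides balance that difference out, and they gave 5 to 19 lists. Some calls at this correlation thus arise without a net group difference. Whether chance alone gives as many as 24 cannot be decided from these splits.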

How the results depend on the processing

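The recovered-fragment, list-permutation, scaled leave-one-out and scaled estimated-correlation fits were chosen after the data were seen. Of 1896 results for named genes under the alternatives, 1840 kept direction and side of the threshold, and 69 of 87 genes did so throughout. Most of these genes were chosen for a large change or a small p in these same data, which favours such stability. Quantile normalization changed the call of 13 named genes and median-of-ratios scaling that of 9. Of all genes called higher as deposited, 3228 did not pass after median-of-ratios scaling. Rnf7 kept its call under every alternative. Median-of-ratios scaling gave 1146 genes higher and 1419 lower, quantile normalization 864 and 1241, removal of mitochondrial-encoded genes 2080 and 711, and voom with median-of-ratios factors 1121 and 1426. These scalings remove the shift of the median by construction, fully or in part. A change of at least 1 on the log2 scale left 236 and 28, and a mean FPKM of at least 5 left 2478 higher and 375 lower, with fewer genes tested. The series of title numbers as a covariate gave 3847 and 478. Leaving out 1 library gave 2897 to 4375 higher and 328 to 451 lower, the 2897 without WT replicate 2. After scaling, leaving out a library gave 670 to 1363 higher and 975 to 1459 lower, with 670 without WT replicate 2, 758 without WT replicate 3, 700 without RBX2iCKO replicate 1 and 733 without RBX2iCKO replicate 2. On deposited values, leaving out 1 library gave log2 differences of Rnf7 from -2.26 to -2.19. In those same fits on deposited values, camera called 5 to 8 lists higher and 17 to 18 lower.

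Lists called higher numbered 10 without a filter, 3 at a mean FPKM of at least 5, 10 after median-of-ratios scaling, 13 after quantile normalization (11 lower) and 10 with voom and those factors. An estimated correlation gave 0 and 0 as deposited and 0 and 0 after scaling, where the smallest adjusted p was 0.126 and 0.228. Fry gave 16 and 5. An exact permutation of list medians put 23 of 44 lists at 0.0286, the smallest it allows, and 0 past adjustment. Each of the 23 had an adjusted p of 0.0547, which the floor and their number fix. The lack of calls in this permutation test is therefore no evidence against any of these lists. Among lists called before or after the change, the direction turned for the cell cycle list at a mean FPKM of at least 5 (-0.11) and the macrophage markers (0.44) after quantile normalization. For mt-Nd1, of equal rank in all libraries, quantile normalization fixes the difference at 0.00 by construction. Among lists called by camera or fry, fry turned other cullins (0.11), SOCS-box receptors (0.13), mitophagy (0.05), NRF2 targets (0.03), proteasome (0.00), atrophy ligases (0.21), circadian clock (0.18) and hypoxia (0.02). Signs also differed for 8 lists that neither called, and after median-of-ratios scaling for 5 lists that camera called neither before nor after. Fry sets a list against 0 and camera against other genes; otherwise the cause was not tested. No paired analysis was possible because the labels give the groups no shared replicate numbers. The sex covariate was not run, since all libraries carry the female pattern.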

Other observations

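The tests of explanations here were chosen after the results were seen. Most cell cycle genes tested rose in the RBX2iCKO ventricles from low levels. Of 29 such genes 25 rose and 1 fell (25 and 1 adjusted over the list alone), and 18 rose after scaling. Cdk1, the mitotic kinase, went from 0.203 FPKM ± 0.0527 to 1.63 FPKM ± 0.671, Top2a from 0.629 to 3.18 FPKM and Rrm2 from 1.04 to 5.17 FPKM (SD, n = 4 each). The gene that fell was Cenpf, singled out after its values were seen. Camera gave an adjusted p = 0.000437, and an adjusted p = 0.597 with an estimated correlation. The list's median, 0.40 above that of all genes, had an exact permutation p = 0.1429, with another split of the libraries at 0.50. RBX2iCKO replicate 1 was highest for Cdk1, Top2a and Rrm2, whose calls held without it, at log2 0.95, 1.05 and 1.27 against 1.09, 1.29 and 1.51. This library also stood apart for erythroid markers, with Alas2 at 42.0 FPKM against 1.872 to 6.204 FPKM in the other 7, and none of the 5 erythroid markers passed. The median of the cell cycle list was -0.11 for its 3 members with a mean FPKM of at least 5. Of 26 cell death genes 17 rose and 0 fell (18 and 0 adjusted over the list alone), including Bak1, 1.53-fold, and Apaf1, 1.81-fold, and after scaling 7 rose and 1 fell. Camera gave an adjusted p = 0.00455, and an adjusted p = 0.415 with an estimated correlation.

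Of 28 inflammation genes 8 rose and 0 fell (7 and 0 adjusted over the list alone, 4 and 0 after scaling), including the NF-kB subunit gene Nfkb1, 1.64-fold, and the chemokine gene Ccl12, 2.64-fold. Camera made no call as deposited (adjusted p = 0.536) and ranked the list above other genes after scaling (adjusted p = 0.0112, and adjusted p = 0.432 with an estimated correlation). Of 27 interferon response genes 5 rose as deposited and 0 after scaling (0 adjusted over the list alone). The list's camera adjusted p was 0.167 as deposited and 0.00014 after scaling, ranked upward, with adjusted p = 0.518 with an estimated correlation. Its median lay 0.76 above that of all genes, with exact permutation p = 0.1143 over 35 splits and another split reaching 0.96 in either direction. Without RBX2iCKO replicate 3 that median was 0.30. That library was highest of the RBX2iCKO libraries for Ifih1 (8.52 FPKM against 3.11 to 3.72), Psmb8 (10.2 FPKM against 3.08 to 5.12) and Irf1 (18.5 FPKM against 9.29 to 13.1). Rsad2 rose by 1.41 on the log2 scale, and by 0.91 without RBX2iCKO replicate 3, where it kept its call (adjusted p = 0.00412, against 0.00412 to 0.098 over its alternatives). Its call was lost after median-of-ratios scaling and without WT replicate 1, 2 or 4. Of 22 genes of endoplasmic reticulum stress 2 rose and 2 fell (2 and 2 adjusted over the list alone), and 9 fell after scaling, with the chaperone genes Hspa5 and Canx falling 1.52-fold and 1.39-fold. Camera gave an adjusted p = 0.000621, and an adjusted p = 0.415 with an estimated correlation. Of 31 proteasome genes 2 rose and 1 fell as deposited (0 and 0 adjusted over the list alone), and 0 rose and 12 fell after scaling. This list ranked below other genes, with camera adjusted p = 0.000127 and adjusted p = 0.441 with an estimated correlation. Hif1a rose 1.76-fold, and the glutathione transferase gene Gstm1 fell 1.40-fold.

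Of 18 genes of mitochondrial biogenesis and dynamics 2 fell and 1 rose (0 and 0 adjusted over the list alone), and 10 fell after scaling. Of 15 NRF2 targets 2 rose and 2 fell, and of 14 hypoxia genes 1 rose and 2 fell, with the same counts adjusted over the list alone. After scaling 0 and 5 NRF2 targets and 1 and 4 hypoxia genes rose and fell. None of the 5 Schwann cell markers passed. Camera ranked these 4 lists below other genes (adjusted p = 4.87e-05, 0.0266, 0.00873 and 0.0347), with adjusted p = 0.141, 0.415, 0.268 and 0.415 with an estimated correlation. The calls on the hypoxia list and the Schwann markers were lost after scaling (adjusted p = 0.0742 and 0.168). Of 19 sarcomere genes 6 rose and 1 fell as deposited (6 and 1 adjusted over the list alone), and 0 rose and 2 fell after scaling, with no camera call (adjusted p = 0.573). Of 21 glycolysis genes 7 rose and 4 fell (8 and 4 adjusted over the list alone), and 1 rose and 8 fell after scaling, where camera ranked the list below other genes (adjusted p = 0.0324, and adjusted p = 0.413 with an estimated correlation), with no call as deposited (adjusted p = 0.107). After scaling camera also ranked above other genes the immediate early genes (adjusted p = 0.0102, against 0.0847 as deposited) and the lymphocyte and neutrophil markers (adjusted p = 0.0262, against 0.536). Their adjusted p was 0.413 and 0.449 with an estimated correlation.

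Esr1 was at 266 to 391 FPKM in the RBX2iCKO libraries and at 0.203 to 2.06 FPKM in the WT libraries. A candidate explanation is that fragments of the Mer-Cre-Mer transgene were counted as Esr1. The estrogen-responsive genes Pgr and Greb1 reached no more than 0.29 FPKM in the RBX2iCKO libraries, as that explanation needs, but such low values do not exclude transcription of the endogenous gene. Under it, an expressed transgene in the WT libraries is argued against, since the lowest RBX2iCKO library was 128.9 times the highest WT library, although the titles of both groups begin with MCM. High Esr1 and low Rnf7 went together in all 8 libraries, with 0 exceptions. Effects of the Cre transgene with tamoxifen and of Rnf7 loss therefore cannot be told apart here, which bears on each difference between the groups. A1cf on chromosome 19, at 0.00 to 0.035 FPKM in WT, was at 0.167 to 0.514 FPKM in RBX2iCKO, below the filter and not tested. Pgr, Greb1, A1cf, Lyz2 and BC002163 were singled out after their values were seen.

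Within both groups, 2 genes fell into separate levels, with a gap of at least 3 on the log2(FPKM + 1) scale and libraries of each group on either side. Lyz2, a macrophage lysozyme gene, was at or under 0.79 FPKM in WT replicate 3, WT replicate 4 and RBX2iCKO replicate 2 and at or over 67.41 FPKM in the others. BC002163 was at or under 2.78 FPKM in 4 libraries and at or over 219.75 FPKM in the others. Rpl34-ps1, a pseudogene also singled out, was at 0.14 and 1.68 FPKM in WT replicates 2 and 1 and at 31.7 to 66.2 FPKM in the other 6 libraries. Xist was present in all 8 libraries and was higher in RBX2iCKO, 26.7 FPKM ± 3.91 against 15.1 FPKM ± 2.53 (SD, n = 4 each).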
